A study of Mus musculus with 12 samples.

How the data were processed

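Poly-A RNA from 12 whole retinas was sequenced as paired-end reads. The libraries form 4 groups of 3 mice each: C57BL/6J and JR5558 at 4 weeks and at 8 weeks of age, each replicate a retina from a separate mouse. The labels leave open whether the libraries were strand-specific, so values of genes that overlap a gene on the other strand are uncertain.

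Per the submitters' processing notes, the authors used fastp, HISAT2 2.0.5 and featureCounts 1.5.0-p3 with the mm10 genome. Per the file headers and the values, the deposited table gives raw counts per gene and library. It also gives FPKM values by the authors, whose method is not stated. The values fit the count over the gene length in bases in the deposited table and over 1 total per library, which was close to but not equal to the sum of the counts. The deposited log2 fold changes, p-values and adjusted p-values come from the authors' own comparisons, whose test is not stated. An adjusted p of 1 stood in the deposited columns where the p-value was missing, for 6 genes in the 4-week strain comparison and 3 in the age comparison of JR5558. The table held 56748 genes, 25020 of them with 0 counts in all 12 libraries, and 882 symbols stood on more than 1 identifier. Gene positions are given as in the deposited table: of 52125 identifiers shared with the GENCODE M21 annotation of the build named in the notes, only 2.92% had the same start and end, so the build of these positions is not settled.

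The counts were analysed with R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and version 1.17.8 of the data.table package. Genes passing edgeR's filterByExpr by group (minimum count 10, minimum total 15) were tested, 18334 in all, which held 99.9% of the counts in each library. Library sizes were scaled by TMM. A quasi-likelihood negative binomial model with 1 mean per group was fitted to all 12 libraries, and 5 contrasts were tested with edgeR's quasi-likelihood test (2-sided): strain at each age, age in each strain, and the difference of the strain effect between ages. P-values were adjusted by the Benjamini-Hochberg method over the tested genes, with a threshold of 0.05. Genes past the threshold with an absolute log2 fold change of at least 1 were counted as well.

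Before the data were examined, 40 gene lists were fixed (pathways, cell type markers and tissues that could be carried over). They hold 771 different genes, 769 of them in the table and 659 tested. Lists with at least 3 tested genes were tested with limma's camera on log2 CPM (counts scaled to a library total of 1e6, prior count 2) with a preset correlation of 0.01, adjusted over the 38 lists tested in this way, and again with a correlation estimated per list. The sex-linked genes and the strain locus genes were counted only. The named-gene rule was also fixed then. It takes the title genes P4ha1, P4ha2, P4ha3, P4hb, Pycr1, Aldh18a1, Prodh, Aldh4a1 and Oat, with Crb1 and Jak3. It takes the 5 genes with the largest change in each direction among those past the threshold, with at least 1 CPM in the higher group and groups that do not overlap, leaving out pseudogenes and unnamed gene models. For each list it takes up to 3 members past the threshold in the order of their adjusted p, or up to 4 for the collagen and proline lists. The age comparisons use the second part and the interaction the first 2 parts. Some genes that the rule selects are not reported here. Genes named outside the rule were chosen after their values were seen, and the text says so.

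Overlap of the strain calls was tested with a 1-sided Fisher exact test per direction. Clustering on chromosomes was tested with a 2-sided Fisher exact test per chromosome and per 10 Mb window. A fold against a group with 0 counts is a lower bound against a floor of 3 counts over the group, and a group with 1 to 3 counts has a ratio with its 95% counting interval. Intervals and floors cover counting error only. Library totals were 18029600 to 23739900 counts.

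The pipeline was tested on simulated data with 18334 genes. At 8 weeks edgeR recovered 26 of 50 genes changed 1.5-fold, 36 of 50 changed 2-fold, 41 of 50 changed 4-fold and 49 of 50 changed 8-fold, with 12 false calls among 167. DESeq2 recovered 28, 37, 42 and 48 of the same genes, with 24 false calls among 188. The totals of 167 and 188 also hold calls of a further planted list of genes with a smaller change, which do not count as false.

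The alternatives chosen before the data were examined were RLE normalization, no filter on low counts, at least 1 CPM in 3 libraries, DESeq2, a fit of only the groups compared, the replicate number as a block, leaving out each library in turn, camera with an estimated correlation, and a log2 fold change of at least 1 for the overlap and the clustering. After the data were seen, fits without the genes of chromosomes X and Y, with a pigment epithelium score as a covariate, and with protein-coding genes only were added. The score is the mean log2 CPM of the fixed pigment epithelium markers, which include Slc6a20a, Slc16a8, Pmel, Dct, Tyrp1 and Krt18. FPKM values and gene lengths were used only for checks of the table, and the reads were not used here.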

Results

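The series measured gene expression in whole retinas of JR5558 mice, an inbred line that forms subretinal new vessels spontaneously and carries the rd8 allele of Crb1 and an allele of Jak3, and of age-matched C57BL/6J mice. There were 4 groups of 3 mice, at 4 and 8 weeks of age. Depth ran from 18029600 to 23739900 counts per library, and rhodopsin, the visual pigment of rods, took 3.61% to 4.13% of the counts. Pearson correlations of log2 CPM were 0.970 to 0.990 within groups and 0.954 to 0.986 between groups. The first principal component of the 500 most variable genes (58.8% of their variance) separated the strains, with C57BL/6J libraries at -25.9 to -23.6 and JR5558 libraries at 19.8 to 32.3. On the second component (11.5%), JR5558 4-week replicate 3 stood apart at 29.0. Errors after ± are standard errors of the log2 fold change for fold changes and SD for CPM, with n = 3 mice per group throughout.

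The groups differed in more than strain and age. The labels give no sex, but the 3 JR5558 retinas of 4 weeks held 2, 5 and 0 counts of Xist, the RNA of the inactive X chromosome, and 1846, 1504 and 1323 counts of the Y-linked gene Ddx3y. The other 9 libraries held 7772 to 22988 Xist counts and 0 counts of Ddx3y, Eif2s3y, Kdm5d and Uty. Rpe65, the visual cycle isomerase of the retinal pigment epithelium, stood at 3.13 to 23.97 CPM in C57BL/6J and 28.0 to 54.5 CPM in JR5558. The mean log2 CPM of the pigment epithelium markers was higher in JR5558 by 1.06 at 4 weeks and 0.80 at 8 weeks (exact permutation test, p = 0.1 each, the smallest that 3 against 3 allows). At each age all JR5558 libraries lay above all C57BL/6J libraries, so a fit with this score as a covariate partly removes strain itself. The lens gene Cryaa ranged from 0 to 62.6 CPM, highest in C57BL/6J 4-week replicate 3.

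At 4 weeks, the comparison asks how the JR5558 retina differs when lesions are young. Camera called lists of Müller glia genes, activated microglia and macrophage genes, pigment epithelium markers and matrix glycoproteins up, although most genes of all but the pigment epithelium and resting Müller glia lists did not pass. None of these list calls held with an estimated correlation (adjusted p = 0.145 for pigment epithelium and 0.137 for the others). Edn2, the endothelin made under photoreceptor stress, rose by a log2 fold change of 2.94 ± 0.31 (adjusted p = 3.67e-06). Lgals3, galectin-3 of activated phagocytes, rose by 2.12 ± 0.25 (adjusted p = 1.29e-05). Crb1 fell by 1.53 ± 0.10 (adjusted p = 5.81e-09), and Pde6c, the cone phosphodiesterase, fell by 2.08 ± 0.09 (adjusted p = 1.15e-11). In all, 1130 of 18334 genes passed the threshold, 599 higher and 531 lower in JR5558, and 394 of them changed at least 2-fold. In 1112 of the 1130 the 3 mice of one strain all lay above the 3 of the other, a separation that chance gives 10% of genes and that 19.6% of the tested genes showed.

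Among the title genes, P4ha1, the catalytic subunit of collagen prolyl 4-hydroxylase (ENSMUSG00000019916, chromosome 10, 59159118 to 59209126), fell at 4 weeks, from 81.9 ± 2.99 CPM in C57BL/6J to 62.5 ± 7.45 CPM in JR5558 (log2 fold change -0.39 ± 0.09, adjusted p = 0.00929). This call ended without JR5558 4-week replicate 2 (adjusted p = 0.0593), with only the 6 libraries compared in the fit (adjusted p = 0.0820) and with the pigment epithelium score as a covariate (-0.55 ± 0.15, adjusted p = 0.106). P4ha2 (-0.26 ± 0.14), P4ha3 (0.32 ± 0.68) and P4hb (0.04 ± 0.08) did not pass, with adjusted p from 0.335 to 0.856. For the enzymes of proline synthesis and breakdown, log2 fold changes were -0.67 ± 0.32 for Pycr1, -0.15 ± 0.10 for Aldh18a1, 0.10 ± 0.12 for Prodh, 0.06 ± 0.14 for Aldh4a1 and 0.18 ± 0.08 for Oat, none past the threshold (adjusted p 0.248 to 0.862). Jak3 (chromosome 8, 72128940 to 72143219) rose from 3.29 ± 0.983 to 8.04 ± 3.65 CPM (1.30 ± 0.27, adjusted p = 0.00529), a call that the pigment epithelium covariate ended (1.16 ± 0.52, adjusted p = 0.364). Crb1 (ENSMUSG00000063681, chromosome 1, 139124794 to 139304838) stood at 502 ± 64.7 CPM in C57BL/6J and 175 ± 26.3 CPM in JR5558.

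Of 21 tested proline metabolism genes, 1 rose and 1 fell at 4 weeks, both over all genes and adjusted over the list alone. They were the proline transporter Slc6a20a (1.63 ± 0.38) and the neutral amino acid transporter Slc38a2 (-0.35 ± 0.09). Slc6a20a is also a pigment epithelium marker, and with that score as a covariate its log2 fold change was -0.24 ± 0.39. The list as a whole was not called (camera adjusted p = 0.950, direction down, with a median of 0.02 and a mean of 0.01). Of 26 genes of collagen hydroxylation and crosslinking, Pcolce, the enhancer of procollagen C-proteinase, rose (1.72 ± 0.21), P4ha1 and Plod2 (-0.51 ± 0.14) fell, and 23 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.233). Of 33 collagens, only Col4a2 of basement membranes passed (0.46 ± 0.13, adjusted p = 0.0344), and 0 passed adjusted over the list alone (camera adjusted p = 0.0610). With the pigment epithelium covariate Col4a2 stood at 0.95 ± 0.19 (adjusted p = 0.0121) and camera called the collagens up (median 0.47, adjusted p = 0.00216). That camera test used the preset correlation only, and was not run with an estimated one. At 8 weeks camera with the same covariate did not call the collagens (adjusted p = 0.0646). Without C57BL/6J replicate 1 or 3 or JR5558 replicate 2 or 3 the Col4a2 call ended (adjusted p up to 0.126), as did that of Slc38a2 without C57BL/6J replicate 3 or JR5558 replicate 2 or 3 (up to 0.157) and that of Plod2 without C57BL/6J replicate 2 or 3 or JR5558 replicate 2 or 3 (up to 0.138). The 21 hypoxia response genes held 1 higher, Car12 (1.98 ± 0.40, or -0.14 ± 0.41 with the pigment epithelium covariate), and 1 lower, Pfkfb3 (-0.42 ± 0.11, ended by leaving out C57BL/6J replicate 1 or 3 or JR5558 replicate 2 or 3, adjusted p up to 0.136), also adjusted over the list alone.

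**Figure D1:**
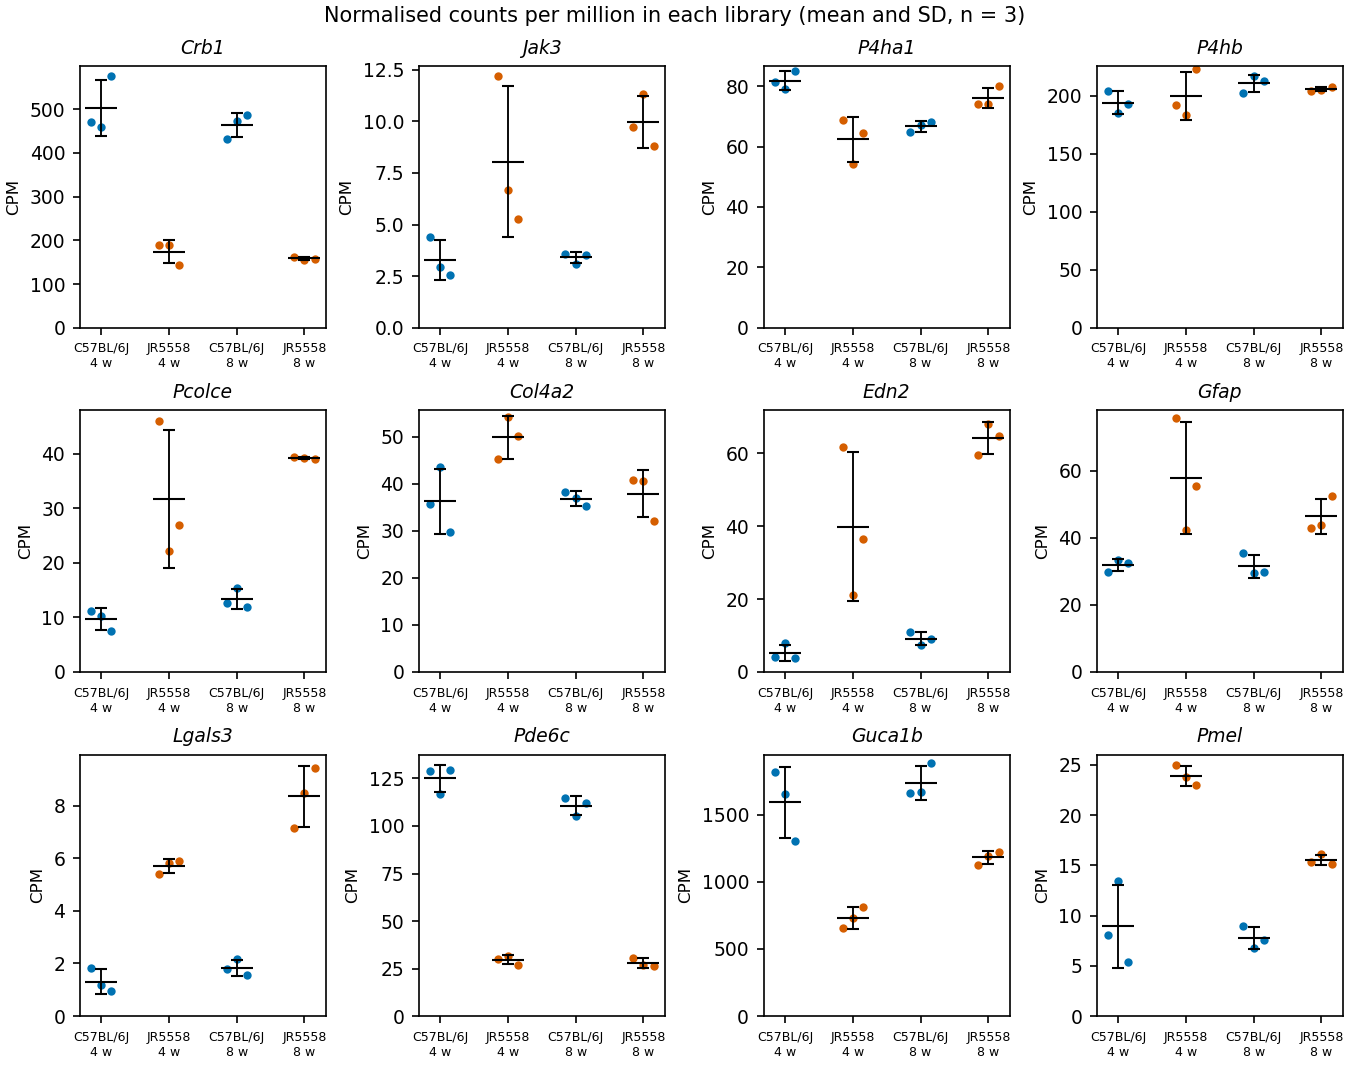
Normalised CPM of 12 genes in each library, with the mean and SD of 3 mice per group. Crb1 stood at a mean of 502 and 464 CPM in C57BL/6J and at 175 and 159 CPM in JR5558 at 4 and 8 weeks, while the P4hb means lay between 194 and 211 CPM.

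The matrix and vessel genes moved in part at 4 weeks. Of 30 matrix glycoproteins and remodelling genes, 5 rose and 0 fell (8 and 0 adjusted over the list alone), among them thrombospondin-1 Thbs1 (1.96 ± 0.24), Tgfbi (1.55 ± 0.33) and Sparc (0.33 ± 0.07). The list was called up (camera adjusted p = 4.33e-05, adjusted p = 0.137 with an estimated correlation). With the pigment epithelium covariate Thbs1 stood at 0.75 ± 0.30, Vim at 0.12 ± 0.13, Cdh2 at 0.09 ± 0.12 and Ramp2 at 0.31 ± 0.31, each call ended (adjusted p = 0.294, 0.749, 0.801 and 0.724). Of 22 TGF-beta and mesenchymal transition genes, Vim (0.43 ± 0.09) and Cdh2 (0.27 ± 0.07) rose, also adjusted over the list alone. Of 24 angiogenesis ligands and receptors, 5 rose and 2 fell, the same adjusted over the list alone, among them the VEGF receptor Kdr (0.72 ± 0.07), Fgf2 (1.84 ± 0.21) and Adamts1 (0.67 ± 0.11). Of 18 endothelial markers only Ramp2 rose (0.60 ± 0.17; 0 adjusted over the list alone), and of 13 pericyte markers only Pdgfrb (0.51 ± 0.11; 1 adjusted over the list alone). Camera called none of these last 4 lists (adjusted p 0.0622 to 0.428). The Cdh2 call ended without C57BL/6J replicate 1 or 2 or JR5558 replicate 1 or 3 (adjusted p up to 0.180), and that of Ramp2 in every leave-one-out fit but the one without JR5558 replicate 2 (up to 0.180).

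Several glial and immune lists were called at 4 weeks. Of 28 reactive Müller glia genes, 9 rose and 0 fell (13 and 1 adjusted over the list alone), including Edn2, the acute-phase inhibitor Serpina3n (1.68 ± 0.26) and Igfbp5 (0.57 ± 0.09). Of 18 resting Müller glia markers, 9 rose and 0 fell (13 and 0 adjusted over the list alone), led by Crym (1.07 ± 0.11), the retinaldehyde-binding protein Rlbp1 (0.72 ± 0.08) and the potassium channel Kcnj10 (0.58 ± 0.08). Both lists were called up (camera adjusted p = 1.05e-07 each, adjusted p = 0.137 each with an estimated correlation). Of 29 genes of activated microglia and macrophages, 7 rose and 1 fell (11 and 1 adjusted over the list alone), with Lgals3, the MHC class II chain Cd74 (1.85 ± 0.34) and the lipase Lpl (-0.63 ± 0.13) first. That list was called up (camera adjusted p = 7.45e-06, adjusted p = 0.137 with an estimated correlation). Of 17 complement genes, 7 rose and 1 fell (9 and 3 adjusted over the list alone): C4b (1.32 ± 0.22) and C3 (1.61 ± 0.29) were higher, and Cd59a, which blocks the membrane attack complex, was lower (-1.86 ± 0.17). Complement (camera adjusted p = 0.0483, adjusted p = 0.219 with an estimated correlation) and MHC class I (1 of 14 higher, H2-D1 at 0.74 ± 0.14, 2 adjusted over the list alone, camera adjusted p = 0.0483, adjusted p = 0.586 with an estimated correlation) were called up. Both calls ended without C57BL/6J replicate 3, JR5558 replicate 1 or JR5558 replicate 3 (adjusted p up to 0.169 and 0.264), and complement also without C57BL/6J replicate 2. With the pigment epithelium covariate the complement (median 0.37 against 0.78, camera adjusted p = 0.738) and MHC class I (median 0.34 against 0.35, 0.397) calls ended, and C3 stood at 0.40 ± 0.40 (adjusted p = 0.726).

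Other glia and immune lists were not called at 4 weeks. Of 13 homeostatic microglia genes 2 rose, with Olfml3 (0.91 ± 0.13) first, the same adjusted over the list alone (camera adjusted p = 0.0610). Of 9 astrocyte markers, 3 rose, the same adjusted over the list alone, with the filament gene Gfap (0.86 ± 0.15) and the water channel Aqp4 (0.33 ± 0.08) first (camera adjusted p = 0.231). The Aqp4 call ended without replicate 1 or 2 of either strain (adjusted p up to 0.109). Both the Gfap call (0.50 ± 0.27, adjusted p = 0.454) and the Aqp4 call (0.14 ± 0.13, adjusted p = 0.690) ended with the pigment epithelium covariate. Of 26 interferon-stimulated genes and 11 cytokines and chemokines, 0 passed by edgeR, over all genes or adjusted over the list alone (camera adjusted p = 0.0541 and 0.428).

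At 4 weeks the rod and cone lists held genes changed in both directions, and the other neuronal lists held few changed genes. Over all tested genes, 1130 of 18334 passed. Of 30 rod genes 1 rose and 3 fell (2 and 3 adjusted over the list alone): Guca1b, a guanylate cyclase activator (-1.12 ± 0.10), and the rhodopsin kinase Grk1 (-0.35 ± 0.06) were lower, and Samd7 was higher (0.43 ± 0.07). The calls of Grk1 (-0.17 ± 0.10, adjusted p = 0.490) and Samd7 (0.45 ± 0.13, adjusted p = 0.127) ended with the pigment epithelium covariate. Of 16 cone genes 2 rose and 3 fell (3 and 3 adjusted over the list alone), with Pde6c lower and Gnb3 (0.70 ± 0.09) and the short-wavelength opsin Opn1sw (0.36 ± 0.07) higher. Neither list was called (camera adjusted p = 0.428 and 0.681). Of 18 bipolar cell markers 2 rose, also adjusted over the list alone, among them the transcription factor Vsx1 (0.54 ± 0.09). The bipolar list was called up (camera adjusted p = 0.0483, adjusted p = 0.154 with an estimated correlation), and only the fit without C57BL/6J replicate 1 kept that call (adjusted p up to 0.106 in the other 5; 0.224 with the pigment epithelium covariate, median 0.10 against 0.08). The ganglion cell gene Pou4f3 (-0.67 ± 0.19), the horizontal cell gene Septin4 (0.41 ± 0.09) and 0 of 17 amacrine markers passed, with the same counts adjusted over the list alone. The Pou4f3 call ended without C57BL/6J replicate 1 or 2 or JR5558 replicate 2 or 3 (adjusted p up to 0.142), and that of Septin4 without JR5558 replicate 2 (0.0526). Of 23 genes of the CRB polarity complex and adherens junctions, Crb1 fell and Cdh2 rose, the same adjusted over the list alone, with a camera adjusted p of 0.969.

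Of 21 pigment epithelium markers, 13 rose and 0 fell (15 and 0 adjusted over the list alone), led by Krt18 (0.62 ± 0.09), the melanosome protein Pmel (1.42 ± 0.21) and Tyrp1 (1.12 ± 0.21), with a median log2 fold change of 1.12 at 4 weeks. Of 17 choroidal fibroblast and melanocyte genes, 5 rose (7 adjusted over the list alone), among them Pmel, Tyrp1 and Dct (1.24 ± 0.24), which are also pigment epithelium markers. Both lists were called up (camera adjusted p = 1.33e-08 and 5.32e-05), with adjusted p = 0.145 and adjusted p = 0.154 with an estimated correlation. The 16 lens genes had a median of -1.46 with 0 past the threshold, also adjusted over the list alone. Camera called them down (adjusted p = 0.0483, adjusted p = 0.752 with an estimated correlation), and the call ended without C57BL/6J replicate 3 or JR5558 replicate 1 or 3 (adjusted p up to 0.802) and with the pigment epithelium covariate (0.397), where the median grew to -1.98.

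Among stress and metabolic lists at 4 weeks, oxidative stress response was called up with 0 of 20 genes past the threshold by edgeR and 3 adjusted over the list alone (camera adjusted p = 0.0112, adjusted p = 0.219 with an estimated correlation; 0.0532 without JR5558 replicate 1 and 0.471 with the pigment epithelium covariate, median 0.11 against 0.16). Glycolysis held 1 lower gene of 21, Eno1 (-0.53 ± 0.06), and 2 higher and 2 lower adjusted over the list alone. Eno1 has a near-identical copy, Eno1b, which was named after its values were seen and was higher in JR5558 (3.60 ± 0.11). Asns (-0.45 ± 0.13) was the only gene of 20 in the integrated stress response list, with 0 adjusted over the list alone. Its call ended without replicate 3 of either strain, C57BL/6J replicate 1 or JR5558 replicate 2 (adjusted p up to 0.198). Of 17 cell death genes, Bcl2 fell (-0.61 ± 0.13) and Tnfrsf1a rose (0.56 ± 0.15; 2 higher and 1 lower adjusted over the list alone), the latter not without replicate 3 of either strain, C57BL/6J replicate 2 or JR5558 replicate 1 (adjusted p up to 0.116). The muscle gene Neb (-2.38 ± 0.45) and the oligodendrocyte gene Cnp (0.42 ± 0.11) passed in lists of 8 and 10, also adjusted over the list alone, Cnp not without replicate 1 of either strain, C57BL/6J replicate 3 or JR5558 replicate 2 (adjusted p up to 0.128). The proliferation (14), blood cell (5), lymphocyte (4) and cornea (4) lists held 0 genes past the threshold by edgeR, over all genes or adjusted over the list alone. Camera called 11 of 38 lists at 4 weeks, and 6 without JR5558 replicate 1.

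The genes with the largest fold changes at 4 weeks include the sex-linked ones. Against 0 counts in C57BL/6J, Ddx3y was at least 1418-fold higher, Eif2s3y at least 1382-fold, Uty at least 578-fold, Kdm5d at least 514-fold and the kallikrein Klk1b22 at least 434-fold. Xist fell by 13.07 ± 0.35 on the log2 scale. Tnfrsf8, with 0 counts in JR5558, was at least 269-fold lower and Trim12a at least 41.0-fold lower. Pttg1 fell by 6.38 ± 0.29, and Zfp429 had a ratio of 80.2 between the strains (95% counting interval 21.8 to 668; 2 counts in JR5558). Pseudogenes made up 69 of the 1130 calls, 49 of them higher in JR5558, and 32 calls lay on chromosome X and 6 on Y. The count of calls was 558 with only the 6 libraries compared in the fit, and 222 with the pigment epithelium score as a covariate. The fit of 6 libraries also ended the calls of Slc6a20a, Sparc, Vim and Pdgfrb. Under that covariate 25 of the 68 named calls stayed past the threshold, while their median absolute log2 fold change went from 0.80 to 0.70 and their median SE from 0.136 to 0.242. Beside the sex-linked genes, the genes named here that kept their call were Cd59a, Col4a2, Crb1, Crym, Edn2, Eno1, Gnb3, Guca1b, Kdr, Klk1b22, Krt18, Lgals3, Pde6c, Pmel, Pttg1, Rlbp1, Tnfrsf8, Trim12a and Zfp429. Krt18 and Pmel are themselves part of the score.

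At 8 weeks, the comparison asks how the strains differ once lesions have matured, and all 6 mice had high Xist. Camera called Müller glia, microglia and pigment epithelium lists up and rod genes down, with 7 of 30 rod genes past the threshold. None of these list calls held with an estimated correlation (adjusted p = 0.193 and 0.253 for the resting and reactive Müller glia lists, 0.174 for both microglia lists, 0.260 for pigment epithelium and 0.457 for rods). Edn2 rose by 2.80 ± 0.29 (adjusted p = 3.34e-06) and Lgals3 by 2.19 ± 0.23 (adjusted p = 4.84e-06). Crb1 fell by 1.55 ± 0.10 (adjusted p = 5.92e-09) and Pde6c by 1.98 ± 0.09 (adjusted p = 2.63e-11). In all, 949 of 18334 genes passed, 466 higher and 483 lower, 344 of them at least 2-fold, and the mice of the strains did not overlap in 948 of them and in 30.2% of the tested genes, against 10% by chance.

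None of the title genes of proline and collagen hydroxylation passed at 8 weeks by edgeR. P4ha1 stood at 66.6 ± 1.78 CPM in C57BL/6J and 76.0 ± 3.35 CPM in JR5558 (log2 fold change 0.19 ± 0.09, adjusted p = 0.261). With only the 6 libraries compared in the fit, P4ha1 was at the edge of the threshold (0.20 ± 0.06, adjusted p = 0.0501). The others were P4ha2 (-0.12 ± 0.14), P4ha3 (-1.29 ± 0.66), P4hb (-0.03 ± 0.08), Pycr1 (-0.44 ± 0.31), Aldh18a1 (-0.15 ± 0.09), Prodh (0.12 ± 0.12), Aldh4a1 (-0.18 ± 0.14) and Oat (0.17 ± 0.08), with adjusted p from 0.302 to 0.874. Jak3 rose from 3.41 ± 0.270 to 9.95 ± 1.26 CPM (1.54 ± 0.27, adjusted p = 0.00122), a call that the pigment epithelium covariate ended (1.44 ± 0.42, adjusted p = 0.115).

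Of 21 proline metabolism genes only the proline transporter Slc6a7 rose at 8 weeks (0.56 ± 0.15, adjusted p = 0.0288; 3 adjusted over the list alone), and only the fit without C57BL/6J replicate 2 kept that call (adjusted p up to 0.146). Of 26 hydroxylation and crosslinking genes only Pcolce passed (1.56 ± 0.20), also adjusted over the list alone. Of 33 collagens 0 passed by edgeR, over all genes or adjusted over the list alone. Camera called none of these 3 lists (adjusted p = 0.535, 0.655 and 0.786), and the 21 hypoxia response genes held 0 past the threshold by edgeR. Of 30 matrix genes 2 rose and 1 fell (4 and 2 adjusted over the list alone): connective tissue growth factor Ccn2 (1.53 ± 0.17) and Thbs1 (1.63 ± 0.25) were higher and osteopontin Spp1 lower (-0.52 ± 0.13). In the TGF-beta list Vim (0.39 ± 0.09) and Cdh2 (0.30 ± 0.07) rose, 2 of 22, also adjusted over the list alone. Of 24 angiogenesis genes 4 rose (6 adjusted over the list alone), with Fgf2 (1.90 ± 0.21), Kdr (0.56 ± 0.07) and Adamts1 (0.55 ± 0.11) first. The calls of Spp1 and Cdh2 ended in each of the 6 fits that left out 1 library (adjusted p 0.0563 to 0.150 and 0.0536 to 0.0794), and that of Vim without replicate 3 of either strain (up to 0.0570). With the pigment epithelium covariate the calls of Thbs1 (0.69 ± 0.25, adjusted p = 0.225), Vim (0.15 ± 0.11, adjusted p = 0.591) and Cdh2 (0.17 ± 0.10, adjusted p = 0.513) ended, while Ccn2 stood at 1.52 ± 0.26 (adjusted p = 0.00279).

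Endothelial markers were lower as a group at 8 weeks, with 1 of 18 past the threshold, the tight junction gene Cldn5 (-0.65 ± 0.14), and 3 lower adjusted over the list alone (median -0.26, camera adjusted p = 0.0207, adjusted p = 0.260 with an estimated correlation). Without C57BL/6J replicate 2 or JR5558 replicate 1 the list call ended (adjusted p up to 0.0600). That of Cldn5 ended without the same libraries or JR5558 replicate 3 (up to 0.0719). Pericyte markers held 0 of 13 past the threshold by edgeR, over all genes or adjusted over the list alone.

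Among immune and glial lists at 8 weeks, activated microglia and macrophages had 8 higher and 2 lower of 29 (12 and 2 adjusted over the list alone), led by Lgals3, the pore-forming Mpeg1 (1.14 ± 0.19) and Laptm5 (0.94 ± 0.18). Homeostatic microglia had 2 higher of 13 (4 adjusted over the list alone), the receptor Csf1r (0.67 ± 0.13) and Olfml3 (0.56 ± 0.13), with a median of 0.56. Both lists were called up (camera adjusted p = 2.88e-05 and 1.32e-05), with adjusted p = 0.174 each with an estimated correlation. Resting Müller glia markers had 7 higher of 18 (13 adjusted over the list alone), with Crym (0.87 ± 0.11), Rlbp1 (0.61 ± 0.08) and the carbonic anhydrase Car14 (0.52 ± 0.10), and reactive genes 8 higher of 28 (11 higher and 1 lower adjusted over the list alone), with Edn2, the transcription factor Cebpd (1.94 ± 0.28) and S100a6 (1.23 ± 0.22). Both were called up (camera adjusted p = 4.57e-07 and 2.88e-05), with adjusted p = 0.193 and adjusted p = 0.253 with an estimated correlation. MHC class I had 2 higher of 14 (3 adjusted over the list alone), H2-D1 (0.96 ± 0.14) and H2-K1 (0.67 ± 0.16), and was called up (camera adjusted p = 0.0234, adjusted p = 0.559 with an estimated correlation), but not without JR5558 replicate 3 (0.172). Complement had 4 higher and 1 lower of 17 (6 and 2 adjusted over the list alone), with Cd59a at -1.45 ± 0.16, C4b at 1.49 ± 0.22 and C1qb at 1.16 ± 0.21, and was not called (camera adjusted p = 0.0525). Of 9 astrocyte markers Aldh1l1 (0.59 ± 0.11) and Gfap (0.56 ± 0.15, adjusted p = 0.0403) rose, also adjusted over the list alone, but Gfap passed in none of the 6 fits that left out 1 library (adjusted p 0.0525 to 0.216). With the pigment epithelium covariate the calls of the homeostatic microglia and reactive Müller glia lists (medians 0.40 against 0.56 and 0.28 against 0.31, camera adjusted p = 0.0646 each), of MHC class I (median 0.20 against 0.36, 0.185) and of Gfap (0.30 ± 0.22, adjusted p = 0.598) ended. So did those of Mpeg1 (0.75 ± 0.28), Laptm5 (0.89 ± 0.27), Csf1r (0.48 ± 0.19), Olfml3 (0.40 ± 0.20), C1qb (0.83 ± 0.31) and H2-K1 (0.42 ± 0.24), with adjusted p from 0.138 to 0.482. The calls of Olfml3 and H2-K1 ended without replicate 2 or 3 of either strain (adjusted p up to 0.102 and 0.118). Interferon-stimulated genes and cytokines held 0 of 26 and 0 of 11 past the threshold by edgeR, over all genes or adjusted over the list alone.

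Of 30 rod genes, 1 rose and 6 fell at 8 weeks (3 and 16 adjusted over the list alone), with Guca1b (-0.56 ± 0.10), the rod transducin Gnat1 (-0.34 ± 0.06) and the channel subunit Cngb1 (-0.41 ± 0.08) first. The rod list was called down with a median of -0.16 (camera adjusted p = 8.46e-05, adjusted p = 0.457 with an estimated correlation), a call that the pigment epithelium covariate ended (median -0.12, adjusted p = 0.103), as it did those of Guca1b (-0.37 ± 0.14, adjusted p = 0.275) and Cngb1 (-0.26 ± 0.12, adjusted p = 0.359) but not that of Gnat1. Of 16 cone genes 2 rose and 2 fell (2 and 4 adjusted over the list alone), with Pde6c lower and Gnb3 (0.58 ± 0.09) and Opn1sw (0.30 ± 0.07) higher. Grm6, the receptor of bipolar cells (-0.36 ± 0.08, 1 of 18), and Tpm3 of the horizontal cell list (-0.38 ± 0.07, 1 of 11) fell, also adjusted over the list alone, and amacrine and ganglion cell markers held 0 of 17 and 0 of 16 past the threshold by edgeR. Of 23 polarity and junction genes Crb1 fell and Cdh2 rose (1 higher and 3 lower adjusted over the list alone). Without replicate 1 of either strain the Opn1sw call ended (adjusted p up to 0.104), as did that of Grm6 without C57BL/6J replicate 1 or 2 or JR5558 replicate 2 or 3 (up to 0.112).

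Of 21 pigment epithelium markers 5 rose at 8 weeks (15 adjusted over the list alone), with Dct (1.11 ± 0.24), Pmel (1.00 ± 0.22) and the lactate transporter Slc16a8 (1.13 ± 0.26) first, and a median of 1.01 (camera adjusted p = 2.19e-06, adjusted p = 0.260 with an estimated correlation). The Pmel call ended without C57BL/6J replicate 2 (adjusted p = 0.0526) and that of Slc16a8 without C57BL/6J replicate 2 or 3 or JR5558 replicate 3 (up to 0.0741). Choroidal genes had 2 higher of 17, Dct and Pmel (3 adjusted over the list alone), and lens genes 0 of 16, neither list being called (camera adjusted p = 0.167 and 0.460). The metallothioneins Mt1 (0.78 ± 0.15) and Mt3 (0.73 ± 0.15) rose, 2 of 20 oxidative stress genes (3 adjusted over the list alone). Mt1 stood at 0.28 ± 0.17 (adjusted p = 0.508) with the pigment epithelium covariate, and the Mt3 call ended without C57BL/6J replicate 2 or JR5558 replicate 3 (up to 0.0654). The integrated stress response list was called down, with the glutathione-degrading Chac1 (-1.35 ± 0.27) and the asparagine synthetase Asns (-0.54 ± 0.13) lower, 2 of 20, also adjusted over the list alone (camera adjusted p = 0.0432, adjusted p = 0.457 with an estimated correlation). That list call ended without C57BL/6J replicate 2 or 3 or JR5558 replicate 1 (adjusted p up to 0.111) and with the pigment epithelium covariate (0.0806, median -0.17 against -0.14), and the Asns call in every fit but the one without C57BL/6J replicate 1 (up to 0.0853). Of 21 glycolysis genes Eno1 fell (-0.65 ± 0.06, with its copy Eno1b, also named after its values were seen, at 3.64 ± 0.11) and 2 rose, with Pgam1 (0.30 ± 0.08) first (4 higher and 1 lower adjusted over the list alone). The Pgam1 call ended in every fit but the one without JR5558 replicate 1 (adjusted p up to 0.135), and with the pigment epithelium covariate (0.18 ± 0.11, adjusted p = 0.521). Bcl2 (-0.60 ± 0.13, 1 of 17 cell death genes) and Neb (-1.72 ± 0.45, 1 of 8 muscle genes) fell. The Bcl2 call ended without C57BL/6J replicate 3 or JR5558 replicate 2 (up to 0.0714) and that of Neb without C57BL/6J replicate 1 or 3 or JR5558 replicate 2 or 3 (up to 0.171). The oligodendrocyte, proliferation, blood, lymphocyte and cornea lists held 0 genes past the threshold by edgeR at 8 weeks.

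The genes with the largest fold changes at 8 weeks mostly stood at or near 0 CPM in 1 strain, for reasons that were not tested. Against 0 counts in C57BL/6J, Klk1b22 was at least 559-fold higher, the carboxylesterase Ces1a at least 98.6-fold and Itprid1 at least 26.3-fold. The testis transcription factor Sox30 rose from 1.05 ± 0.267 to 40.3 ± 3.27 CPM (log2 fold change 5.24 ± 0.21). Tnfrsf8 was at least 263-fold lower and Trim12a at least 48.1-fold lower, with 0 counts in JR5558. Pttg1 (-5.04 ± 0.25), Zfp982 (-4.80 ± 0.69) and the fatty acid receptor Ppara (-4.72 ± 0.34) fell. Pseudogenes made up 55 of the 949 calls, 44 of them higher. The count of calls was 2183 with only the 6 libraries compared in the fit and 324 with the pigment epithelium covariate. With that covariate 28 of the 61 named calls stayed past the threshold. Over the 61, the median absolute log2 fold change was 0.83 against 0.96 in the main fit, and the median SE 0.223 against 0.154. The genes named here that kept their call were C4b, Ccn2, Cd59a, Cebpd, Ces1a, Crb1, Crym, Edn2, Eno1, Fgf2, Gnat1, Gnb3, H2-D1, Kdr, Klk1b22, Lgals3, Pcolce, Pde6c, Pmel, Ppara, Pttg1, Rlbp1, Sox30, Spp1, Tnfrsf8, Trim12a and Zfp982. Pmel is itself part of the score. The count of calls was 538 without JR5558 replicate 3, 583 without JR5558 replicate 2, 602 without C57BL/6J replicate 1 and 632 without C57BL/6J replicate 2.

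Many strain calls were shared between the ages, which have no library in common. Of the calls, 292 were higher at both ages and 265 lower at both ages, against 15.2 and 14.0 that independent lists would share (1-sided Fisher exact tests, log10 p of -339 and -300), and 1 gene was called in opposite directions. These tests take genes as independent units, although the shared calls lay in clusters on the chromosomes. Both comparisons also use the same estimate of the spread of each gene, so independent lists are only a rough reference. Of the 4-week calls 91.2% had the same sign at 8 weeks, and of the 8-week calls 93.9% had the same sign at 4 weeks. Spearman's rho of the fold changes was 0.36 across all 18334 tested genes and 0.85 across the 1521 genes called at either age, which were selected by their calls and are not independent replicates. Crb1, Pde6c, Edn2, Lgals3, Pcolce, Fgf2, Rlbp1, Klk1b22 and Tnfrsf8 were among the genes called in the same direction at both ages.

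**Figure D2:**
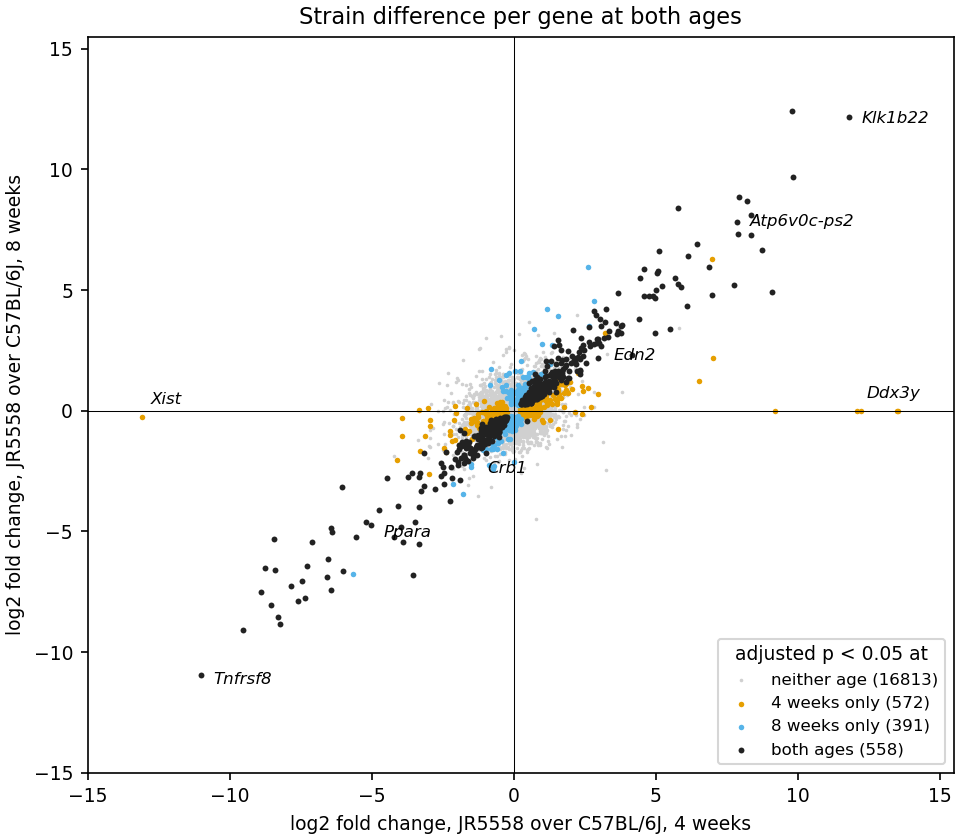
Log2 fold change of JR5558 over C57BL/6J at 4 weeks (horizontal) and 8 weeks (vertical) for each tested gene, coloured by the ages at which its adjusted p was under 0.05. Of the 558 genes past the threshold at both ages all but 1 changed in the same direction, while Xist and Ddx3y changed at 4 weeks only.

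Genes called at both ages in the same direction lay in clusters on the chromosomes. Of 555 such genes with a position among 18298 tested (3.03%), chromosome 8 held 54 of 985, chromosome 14 held 35 of 620, chromosome 17 held 45 of 899, chromosome 18 held 33 of 528 and chromosome 4 held 49 of 1123, each above the rest (Fisher exact tests, adjusted p 0.000436 to 0.0288). Chromosomes 1 (13 of 1087), 12 (5 of 688) and 3 (12 of 937) held fewer (adjusted p 0.000436 to 0.00188). With DESeq2 calls the result for chromosome 4 ended (adjusted p = 0.151). With a log2 fold change of at least 1 those for chromosomes 4 (0.323), 8 (0.0519), 1 (0.0519) and 3 (0.0574) ended. Of 273 windows of 10 Mb, 13 held more than the rest and 1 held fewer. The window of chromosome 4 from 140 to 150 Mb, which holds Tnfrsf8 and Zfp982, had 20 of 112 genes called. That of chromosome 8 from 30 to 40 Mb had 11 of 42. The window of chromosome 8 from 70 to 80 Mb, which holds Jak3, had 17 of 149. Of 246 windows with at least 20 tested genes, 73 held 0 called genes.

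Several pseudogenes higher in JR5558 had a lower parent gene. At 8 weeks Atp6v0c-ps2 had a log2 fold change of 7.32 and its parent Atp6v0c, a subunit of the vacuolar proton pump, a log2 fold change of -1.42. The copy gained 225 CPM and the parent lost 222 CPM. The gain and loss were 62.9 and 56.4 CPM for Ndufs5, 45.9 and 91.6 CPM for Rnps1, and 115 and 184 CPM for Rpl3 with 2 copies. Ndufs5-ps (7.30) and the mitochondrial complex I gene Ndufs5 (-2.16), Rnps1-ps (6.91) and the splicing gene Rnps1 (-1.56), and Rpl3-ps1 (2.17) and the ribosomal protein gene Rpl3 (-0.83) showed the same opposite signs. These pairs were chosen after the values were seen.

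**Figure D3:**
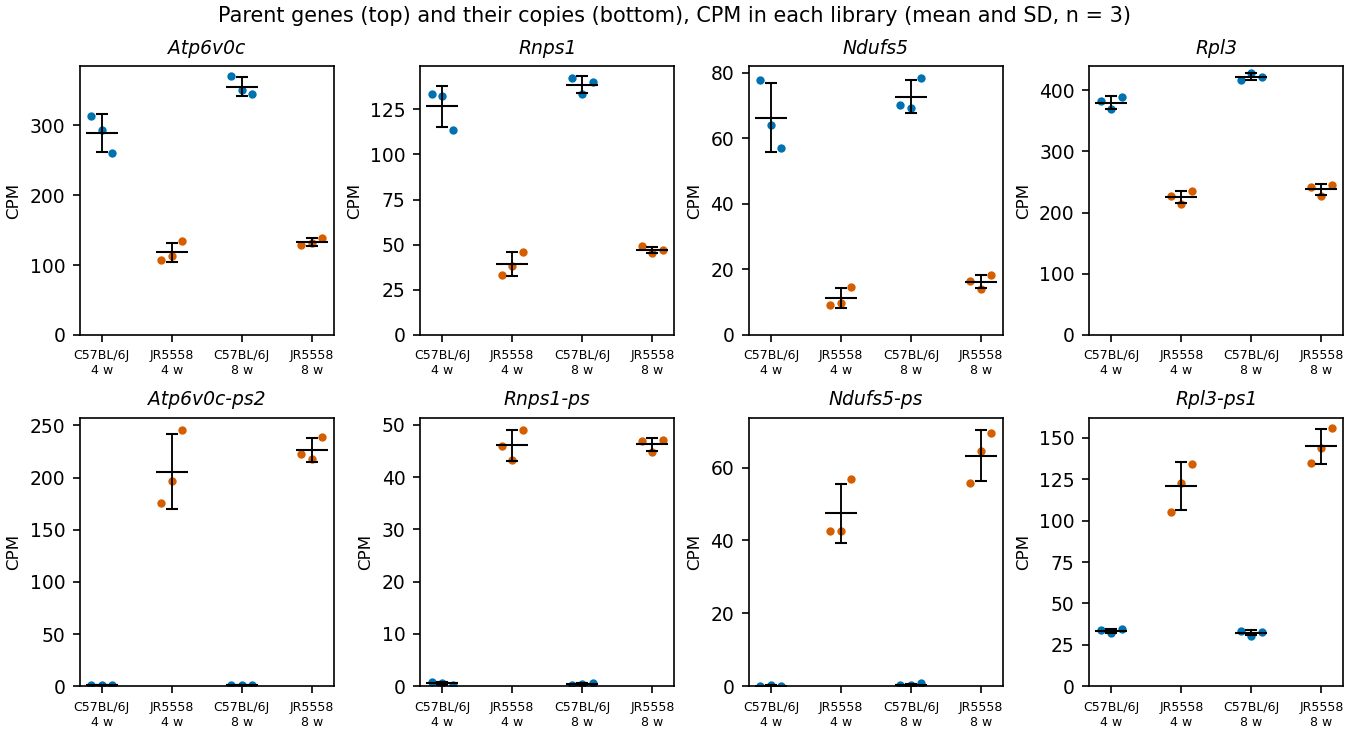
Normalised CPM per library of 4 parent genes and of their pseudogene copies, with the mean and SD of 3 mice per group. In JR5558 the copy of Atp6v0c rose by 225 CPM at 8 weeks while Atp6v0c itself lost 222 CPM.

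The interaction asks which strain differences changed from 4 to 8 weeks. Only the JR5558 mice of 4 weeks were male by Xist and Y-linked genes, so it cannot separate age from sex. This limit holds for every gene and list given for the interaction. The bipolar cell transcription factor Vsx1 stood at 37.8 ± 2.92 CPM in C57BL/6J and 55.05 ± 4.29 CPM in JR5558 at 4 weeks, and at 47.9 ± 3.30 and 42.6 ± 2.27 CPM at 8 weeks, a difference of -0.71 ± 0.13 (adjusted p = 0.0435). The strain effect was also lower at 8 weeks for the amino acid transporter Slc38a3 (-0.61 ± 0.10), the histone gene H3f3b (-0.67 ± 0.11) and Arrdc3 (-0.70 ± 0.13). It was higher at 8 weeks for the thyroid hormone deiodinase Dio2 (1.82 ± 0.28), Etnppl (1.45 ± 0.22), Ip6k2 (1.37 ± 0.20) and the mitochondrial tRNA mt-Tl2 (1.93 ± 0.36). With the change of sex between the JR5558 groups, it was also higher for Xist (12.84 ± 0.41). In all, 17 genes passed, 10 with a higher and 7 with a lower strain effect at 8 weeks, and 5 lay on chromosome X. The count was 63 by DESeq2, 96 with no filter on low counts and 9 without the genes of chromosomes X and Y. It was 38 without C57BL/6J 4-week replicate 3, 32 without JR5558 4-week replicate 3, 9 without JR5558 4-week replicate 2, 10, 6 and 11 without C57BL/6J 8-week replicates 1, 2 and 3, and 10, 8 and 11 without JR5558 8-week replicates 1, 2 and 3.

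Of the title genes, P4ha1 had the largest difference of the strain effect relative to its error (0.58 ± 0.12), and it did not pass with edgeR (adjusted p = 0.118). It passed with DESeq2 (0.58, adjusted p = 0.00435) and with no filter on low counts (0.60, adjusted p = 0.00660). P4ha3 stood at -1.61 ± 0.95, Crb1 at -0.02 ± 0.14 and Jak3 at 0.24 ± 0.38, and P4ha2, P4hb, Pycr1, Aldh18a1, Prodh, Aldh4a1 and Oat lay between -0.24 and 0.22, with adjusted p from 0.765 to 1.00. The Dio2 call ended without C57BL/6J 8-week replicate 2 (adjusted p = 0.0585). That of H3f3b ended without C57BL/6J 8-week replicate 2 or 3, JR5558 4-week replicate 2 or JR5558 8-week replicate 1 or 2 (adjusted p up to 0.0781), and that of Slc38a3 without C57BL/6J 8-week replicate 1 or 2, JR5558 4-week replicate 2 or JR5558 8-week replicate 2 or 3 (up to 0.0654). With 1 library left out, Vsx1 passed only without C57BL/6J 4-week replicate 3 (adjusted p up to 0.241 in the other fits). The call of mt-Tl2 was kept only without C57BL/6J 4-week or 8-week replicate 3 (up to 0.230), and that of Arrdc3 only without replicate 3 of either strain at 4 weeks (up to 0.277).

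Camera called 7 lists for the interaction. For 6 of them the strain effect, JR5558 against C57BL/6J, was lower at 8 weeks than at 4 weeks. Among these were endothelial markers (median -0.39, adjusted p = 0.00448, adjusted p = 0.184 with an estimated correlation), pericyte markers (median -0.32, adjusted p = 0.0107, adjusted p = 0.183 with an estimated correlation) and bipolar markers (adjusted p = 0.0107, adjusted p = 0.183 with an estimated correlation). The others were choroidal genes (adjusted p = 0.0155, adjusted p = 0.651 with an estimated correlation), rod genes (adjusted p = 0.0186, adjusted p = 0.759 with an estimated correlation) and matrix genes (adjusted p = 0.0498, adjusted p = 0.651 with an estimated correlation). For lens genes the strain effect was higher (median 1.94, adjusted p = 0.00570, adjusted p = 0.760 with an estimated correlation). Over all genes, 2 bipolar markers, Vsx1 among them, were the only members past the threshold. Adjusted over the list alone, the strain effect was lower at 8 weeks for 2 endothelial, 2 pericyte and 3 bipolar markers. By the same count it was higher for 2 and lower for 4 rod genes, and higher for 1 and lower for 2 matrix genes. The bipolar call ended without replicate 3 of either strain at 4 weeks (adjusted p up to 0.0556) and the pericyte call without JR5558 4-week replicate 1 (0.0528). The choroidal, lens and matrix calls each ended without C57BL/6J 4-week replicate 3, C57BL/6J 8-week replicate 1, JR5558 4-week replicate 1 or JR5558 8-week replicate 1 (up to 0.174, 0.302 and 0.174), the lens call also without JR5558 4-week replicate 3 and the matrix call without JR5558 8-week replicate 3. The rod call ended without replicate 2 or 3 of either strain at 4 weeks, C57BL/6J 8-week replicate 3 or JR5558 8-week replicate 1 (up to 0.159). The count of lists was 4 without C57BL/6J 8-week replicate 1 and 3 without JR5558 replicate 1 of either age.

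In C57BL/6J, the change from 4 to 8 weeks addresses maturation of the control retina. The extracellular peroxidase Gpx3 rose from 42.1 ± 14.3 to 128 ± 5.36 CPM (log2 fold change 1.61 ± 0.23), and Hdc, which makes histamine, from 13.4 ± 1.47 to 28.5 ± 2.38 CPM (1.09 ± 0.15). Isyna1 of inositol synthesis (0.98 ± 0.10), Hmgb2 (0.97 ± 0.12) and Pabpn1l (1.48 ± 0.28) rose, and Duxbl1 (-1.73 ± 0.27), Capn11 (-1.68 ± 0.31), Ccdc187 (-1.29 ± 0.24), the copper transporter Atp7a (-1.06 ± 0.19) and Lcor (-0.92 ± 0.14) fell. In all, 79 genes passed, 37 higher and 42 lower, 11 of them at least 2-fold. Rod genes were called up, with 3 higher and 1 lower of 30 (9 and 3 adjusted over the list alone, camera adjusted p = 0.00181, adjusted p = 0.666 with an estimated correlation), as was the integrated stress response list with 0 of 20 past the threshold by edgeR (5 higher adjusted over the list alone, camera adjusted p = 0.000519, adjusted p = 0.383 with an estimated correlation). Resting Müller glia, interferon, cytokine, MHC class I, oxidative stress and complement lists were also called up and blood cell genes down (camera adjusted p 0.00781 to 0.0443, each with adjusted p = 0.383 or adjusted p = 0.666 with an estimated correlation). The calls of Duxbl1 and Lcor ended without 8-week replicate 2 (adjusted p = 0.0683 and 0.0655), that of Atp7a without each of the 8-week replicates in turn (up to 0.0941) and that of Capn11 without 4-week replicate 1 or 8-week replicate 1 or 2 (up to 0.162). Those of Ccdc187 and Pabpn1l ended without 4-week replicate 2 and without each of the 8-week replicates (up to 0.106 each), and that of Pabpn1l also without 4-week replicate 3. The count was 365 by DESeq2, 445 with no filter, 22 with only these 6 libraries in the fit, 125 and 38 without 4-week replicates 1 and 2, and 31, 16 and 27 without 8-week replicates 1, 2 and 3.

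In JR5558, the change from 4 to 8 weeks follows the lesions in time but also goes from male to female libraries by Xist and Y-linked genes. Some vessel and matrix genes fell. Of 18 endothelial markers 3 fell (8 adjusted over the list alone), and of 13 pericyte markers 3 fell (1 higher and 7 lower adjusted over the list alone). Both lists were called down (camera adjusted p = 4.61e-06 and 0.00209, adjusted p = 0.0875 each with an estimated correlation). Chosen after their values were seen, Eng (-0.72), Pecam1 (-0.56), Rgs5 (-0.60), Abcc9 (-1.20) and Pdgfrb (-0.48) were among the members that fell. Blood cell genes (2 of 5 lower, 4 adjusted over the list alone, camera adjusted p = 0.00209, adjusted p = 0.323 with an estimated correlation), bipolar markers (2 of 18 lower, 1 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.00719, adjusted p = 0.0915 with an estimated correlation) and matrix genes (1 higher and 4 lower of 30, 3 and 9 adjusted over the list alone, camera adjusted p = 0.0254, adjusted p = 0.323 with an estimated correlation) were called down. Glycolysis (2 of 21 higher, 4 adjusted over the list alone, camera adjusted p = 0.00571, adjusted p = 0.564 with an estimated correlation), MHC class I, lens and complement lists (camera adjusted p 0.0159 to 0.0429, and adjusted p 0.323 to 0.639 with an estimated correlation) were called up.

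Among named genes of the JR5558 age comparison, Hdc (1.84 ± 0.21), Etnppl (1.60 ± 0.16), Shisal2b (2.13 ± 0.30), mt-Tl2 (1.98 ± 0.26) and Xist (12.05 ± 0.35) rose. The apelin receptor Aplnr fell by 3.94 ± 0.79, a call that ended without JR5558 4-week replicate 1 or 2 or 8-week replicate 1 or 3 (adjusted p up to 0.134). Ddx3y was at least 1567-fold lower, Eif2s3y at least 1527-fold, Uty at least 638-fold and Kdm5d at least 568-fold. In all, 277 genes passed, 124 higher and 153 lower, 48 of them at least 2-fold. The count was 690 by DESeq2, 854 with no filter, 544 with only these 6 libraries in the fit, 146, 96 and 689 without 4-week replicates 1, 2 and 3, and 138, 93 and 63 without 8-week replicates 1, 2 and 3.

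The authors' deposited comparisons listed 752 genes with an adjusted p under 0.05 between strains at 4 weeks, 2088 at 8 weeks, 156 between ages in C57BL/6J and 1028 between ages in JR5558. They share 738, 923, 74 and 272 genes with the calls above, each of these in the same direction. For P4ha1 at 4 weeks the deposited log2 fold change was -0.39 with an adjusted p of 0.0317, at 8 weeks 0.19 (0.0564), with age in C57BL/6J -0.30 (0.101) and with age in JR5558 0.29 (0.0495).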

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

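The share of 4-week calls with the same sign at 8 weeks, the reverse selection of 8-week calls, the comparison of parents with their copies, the counts over distinct parents, the CPM of single pairs and the score as a covariate were chosen after the result was seen, and the other tests of this part were fixed before their values were computed.

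Sex and strain could not be separated at 4 weeks, where only the JR5558 mice lacked Xist and expressed Y-linked genes. If male sex made the autosomal calls of 4 weeks, their direction would be lost at 8 weeks, where all mice had Xist, yet 91.7% of the 1092 autosomal calls kept their sign (exact 95% interval 89.9 to 93.2), which speaks against sex as their main source. For the 544 autosomal genes called at 4 weeks only, the median fold change at 8 weeks was 0.393 of that at 4 weeks (95% bootstrap interval 0.350 to 0.434), with 83.5% of the same sign. The reverse selection, 391 genes of all chromosomes called at 8 weeks only, had a median of 0.49 at 8 weeks and 0.20 at 4 weeks, against 0.51 at 4 weeks and 0.20 at 8 weeks for the 544, and 85.4% of the same sign. Selection on the threshold could therefore give a shrinkage of this size without sex, and this test leaves the share of sex or age open.

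Pseudogene copies higher in JR5558 may hold reads of their parent gene if the strain differs in sequence from the reference. Of 15 copies past the threshold and higher at both ages, 13 had a parent that was lower at both ages, counted by sign alone. This held for 32.9% of the parents of 164 other copies. A parent past the threshold and lower at both ages stood beside 6 of the 15 copies and 2 of the 164. Because 3 parents have 2 copies each, the count by sign over distinct parents is 10 of 12 (exact 95% lower limit 51.6%). For 13 of 15 pairs, and again 10 of 12 distinct parents, the summed CPM at 8 weeks rose by under 0.5 of the copy's gain. These were the same parents that were lower at both ages, so this count is no separate evidence. Where the parent is far more abundant than the copy, a small fall of the parent is enough for this outcome. Rps15a, for example, lost 26.1 CPM against a gain of 3.16. The count therefore cannot decide whether a copy was transcribed beside an unchanged parent. The falls of Atp6v0c and Ndufs5 were close to the gains of their copies and could be a matter of counting. But Rnps1 lost 91.6 CPM against a gain of 45.9 and Rpl3 lost 184 against 115. Eno1 went from 2717 to 1730 CPM while Eno1b went from 53.0 to 662 CPM, so part of these falls has no matching gain and remains open.

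Pigment epithelium markers were higher in JR5558 at both ages, which could come from more pigment epithelium carried over or from a change within its cells. Within groups the 21 markers moved together across mice, with a mean pairwise correlation of 0.226 against -0.0370 to 0.0666 in random lists matched on expression. This was predicted for a varying share of pigment epithelium, but markers regulated together within the cells could give it too. It rests on deviations within groups, so it does not tell why the strains differ. The fold changes of the markers at 8 weeks had an SD 1.33 times their median standard error, a spread that leaves a change within the cells open. The mean score differed by 0.80 between the strains at 8 weeks, where it was 3.07 to 3.65 in C57BL/6J and 4.06 to 4.42 in JR5558. The largest range within a group, 0.926, was that of C57BL/6J at 4 weeks, where the strains differed by 1.06. Genes such as Thbs1 and C3 lost their 4-week call with the score as a covariate. Because the score separated the strains at each age, whether these genes reflect tissue carried over remains open.

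The 10 splits of 6 libraries are too few for a share under 0.05. The real grouping was 1 of 10 splits with as many genes at 4 weeks (1130, highest other 3), 1 of 10 at 8 weeks (949, highest other 0), 1 of 10 for age in C57BL/6J (79, highest other 0) and 1 of 10 for age in JR5558 (277, highest other 0). For the interaction, 4 of 100 drawn assignments of the ages within each strain gave at least the 17 genes found, the real assignment included. The others, with 29, 224 and 1016 genes, exchanged the ages of all JR5558 libraries and kept those of most or all C57BL/6J libraries. They so tested largely the age change that the strains share, and 4 of 100 is not a share expected without an interaction.

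The strain effect differed between the ages by 12.84 for Xist, 1.37 for Ip6k2, 1.45 for Etnppl, 1.82 for Dio2, -0.67 for H3f3b, -0.61 for Slc38a3, -0.71 for Vsx1, 1.93 for mt-Tl2 and -0.70 for Arrdc3 on the log2 scale. Only the JR5558 mice of 4 weeks were male by Xist and Y-linked genes, so age and sex cannot be told apart in these differences or in the lists. For lists the camera adjusted p was 0.00448 for endothelial markers, 0.00570 for lens genes, 0.0107 for pericyte and for bipolar markers, 0.0155 for choroidal genes, 0.0186 for rod genes and 0.0498 for matrix genes. With an estimated correlation 0 of these lists passed (adjusted p = 0.183 to 0.760).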

How the results depend on the processing

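The fits without chromosomes X and Y, with the pigment epithelium score and with protein-coding genes only were chosen after the data were seen. Where a count moved, the cause was not tested. The 1130 strain calls at 4 weeks were 558 with only the groups compared and 222 with the pigment epithelium score as a covariate, and the 949 at 8 weeks were 2183 and 324, and 538 to 649 when 1 library was left out. In both of those fits more genes passed at 8 weeks than at 4 weeks, the reverse of the main fit. The main fit shares its estimate of the spread among all groups, so the counts do not rank the ages. The 17 interaction calls were 96 with no filter, 63 with DESeq2, 9 without chromosomes X and Y and 6 to 38 when 1 library was left out. The 79 calls for age in C57BL/6J were 445 with no filter, 365 with DESeq2, 22 with only the groups compared and 16 to 125 when 1 library was left out, and the 277 for age in JR5558 were 854, 690, 544 and 63 to 689. With an estimated correlation the called lists went from 11 at 4 weeks, 9 at 8 weeks and 7 for the interaction to 0 each. They were 6 and 3 at 4 and 8 weeks with the pigment epithelium score, and 6 to 12 at 4 weeks and 3 to 8 for the interaction when 1 library was left out. The overlap of 557 genes was 253 and the 8 chromosomes were 4 with a log2 fold change of at least 1. With the pigment epithelium score as a covariate the sign turned for Slc6a20a (-0.24) and Car12 (-0.14) at 4 weeks and for Slc16a8 (-0.0094) at 8 weeks, and for the pigment epithelium list, with an adjusted p of 0.739 at 4 weeks and 0.559 at 8 weeks by camera. Slc6a20a, Slc16a8 and that list are part of the score itself. RLE normalization kept 188 of 190 named gene results and all 27 called lists.

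With the replicate number as a block, 181 of 190 named gene results and all 27 called lists were kept. Libraries with the same replicate number were not paired by their values: 2 of 12 libraries were closest to one with their own number, and the correlations of deviations had a median of -0.00386 for the same number and -0.00153 for other numbers.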

Other observations

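Genes in this part were chosen after their values were seen. They are single genes outside the fixed lists, and no gene group was tested. Hdc, the histamine-making enzyme, fell in JR5558 (log2 fold change -3.31 ± 0.19 at 4 weeks, adjusted p = 8.49e-10, and -2.56 ± 0.16 at 8 weeks, adjusted p = 3.48e-09). Nxnl1, which encodes the rod-derived cone viability factor, fell (-0.63 ± 0.07 and -0.75 ± 0.07), and lies in the window of chromosome 8 that holds Jak3. Impg2, a proteoglycan of the matrix around photoreceptors, rose (1.08 ± 0.09 at both ages). The GABA receptor subunit Gabra2 (1.29 ± 0.12 and 1.48 ± 0.12) and the kinase Camk2a (0.61 ± 0.08 and 0.76 ± 0.08) rose, and the nicotinic receptor modulator Lynx1 fell (-0.78 ± 0.09 and -0.87 ± 0.09).

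Ppara, a nuclear receptor that drives fatty acid oxidation, fell to near 0 (-5.02 ± 0.32 at 4 weeks and -4.72 ± 0.34 at 8 weeks), and genes of fatty acid oxidation were looked up beside it, of which 3 are given here, which is no test of its targets. Cpt1a was lower at 8 weeks (-0.28 ± 0.08, adjusted p = 0.0401) but not at 4 weeks (adjusted p = 0.518), and Acadm (adjusted p = 0.349 and 0.851) and Hadha (0.903 and 0.763) did not pass at 4 and 8 weeks. From 4 to 8 weeks Usp2 (0.84 ± 0.09), Ciart (0.91 ± 0.12), Per1 (0.52 ± 0.12) and Dio2 (1.30 ± 0.19) rose in JR5558. The clock genes Dbp (adjusted p = 0.274), Nr1d1 (0.418), Arntl (0.383), Per3 (0.552), Cry1 (0.194) and Cry2 (0.275) did not pass in that comparison.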
